A study of Homo sapiens with 6 samples.

How the data were processed

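ARPE-19, an established human retinal pigment epithelial cell line, was transfected in 6-well plates with 2.5 µg per well of either a GFP plasmid, which served as the control, or a plasmid carrying GFP together with satellite alpha, the repeat DNA of human centromeres. Per the labels' protocols each transfection was done in triplicate, total RNA was isolated on columns, and biotin-labelled targets were made with an Affymetrix kit for 3′ expression arrays. The 6 arrays fell into 3 GFP and 3 SATalpha arrays by their labels. The labels did not say whether the 3 wells of a group came from separate cultures or days, so p-values measure the spread between these wells, which may be partly technical. The labels and the files used here gave no scan date or processing batch, so an effect of batch could not be checked apart from group.

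The deposited values were on a log2 scale and already normalized between arrays by the authors. The base was read from the values, since a natural logarithm of a 16-bit scanner value cannot reach the array maxima seen here. The submitters' processing notes name MAS5 and RMA without saying which made the deposited log2 values. The near-equal quantiles of the 6 arrays are what RMA produces, but the method remains unknown. Versions, filters and background settings are not given in the sources used here. RMA compresses small differences of dim transcripts toward 0, so log2 differences of dim genes may be understated. Scanner files were not used here, so no detection call was available and signal could not be set against background.

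The table held 49372 probe sets, of which 79 were Affymetrix controls. Gene names came from the platform annotation given with the series. In it, 44988 of the other probe sets had 1 gene symbol, 1832 had several and 2473 were not listed. The last 2 kinds entered no gene-level test and are reported only as counts and by probe set. Symbols were compared with current names through the gene identifiers, and 0 needed an update. Each of 18132 genes was represented by its probe set with the highest mean over the 6 arrays, and the lowest 40% of genes by mean were left out, which put the floor at a mean log2 level of 5.19. This left 10879 tested genes. No genome build is named for these values, so no coordinates are given.

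Groups were compared as SATalpha minus GFP with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors (SE) are limma's moderated ones. Single measures of array quality were compared with a two-sided exact permutation test, for which 3 against 3 arrays cannot give a p below 0.1. The number of arrays limits the precision, and the median SE of a log2 difference was 0.06.

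Gene groups were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry beside it. The lists numbered 31 and held 715 distinct genes, of which 656 had a probe set with 1 symbol and 560 were tested. The remaining members were not analysed here. They covered cell identity, responses to nucleic acid, cell cycle, centromere, chromatin, stress, metabolism, matrix and 3 other cell types. The 28 lists with at least 5 tested genes were tested as sets, and their p-values were adjusted over those 28. Camera compares a list with all other tested genes. In fry, the directional p tests whether the members move one way on balance without comparing them with other genes.

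Genes were named by a rule. It took the 10 largest increases and the 10 largest decreases among genes past the threshold whose groups did not overlap. It added up to 4 members of each list past the threshold by smallest p, or up to 2 members as values where none passed. CENPA, CENPB, CENPC, SUV39H1, CDH1, CDH2, VIM and RPE65 were named wherever tested. The lists, the rule, the test and the alternatives were fixed before the data were examined. Genes named outside the rule are marked as chosen after their values were seen.

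The test was tested on simulated data for SATalpha minus GFP over 10879 genes, in 10 simulations with 200 changed genes each. It recovered 38.2% of genes changed by 1.2-fold, 90.6% of those changed by 1.5-fold and 98.5% of those changed by 2-fold. Of the simulated calls, 3.29% were false. With no simulated change the mean number of calls was 0, and 4% of random lists had a camera p under 0.05. The simulated noise was drawn separately for each gene. The 4% therefore does not show how camera behaves for lists whose members vary together.

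Alternatives were another filter or none, quantile normalization, median centring, the mean of all probe sets of a gene, leaving out probe sets that can match several transcripts, the replicate number as a block, each array left out in turn, no variance trend, array weights, probe sets in place of genes, an unmoderated test, and an added fold threshold of 1.5. Groups of genes chosen after seeing the data were tested separately. Figures were drawn with matplotlib 3.10.9.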

Results

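The series compared gene expression in ARPE-19 cells between cells given a GFP plasmid that carries satellite alpha repeats and cells given the GFP plasmid alone. It held 6 arrays, 3 per plasmid. Array medians lay between 5.29 and 5.31 on the log2 scale. Correlations across probe sets were 0.996 to 0.997 within a group and 0.995 to 0.996 between groups, although probe sets are not independent replicates. The first principal component took 56.6% of the variance and separated the groups, and the second took 19.0%.

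The difference between the 3′ and 5′ control probe sets of GAPDH was 0.393 ± 0.046 with GFP and 0.393 ± 0.068 with satellite alpha (SD, n = 3, exact permutation p = 1). For ACTB it was 2.06 ± 0.07 and 2.02 ± 0.13 (SD, n = 3, exact permutation p = 0.6). The bioB hybridization spike averaged 8.70 ± 0.09 and 8.54 ± 0.10 (SD, n = 3, exact permutation p = 0.2). An Alu control probe set was at 13.78 ± 0.0065 and 13.76 ± 0.0067 (SD, n = 3, exact permutation p = 0.1), with the 3 satellite alpha values below the 3 GFP values by a small margin. That p is the smallest this design allows, so none of these 4 measures could pass 0.05.

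Satellite alpha was accompanied by lower mitotic genes and higher interferon-stimulated genes, and the clock repressors BHLHE41 and CIART were among the largest decreases. Both gene lists were called by camera with a preset correlation, and both calls were lost with an estimated correlation (adjusted p = 0.145 for G2/M and mitosis and adjusted p = 0.190 for interferon-stimulated genes). Of 10879 tested genes, 2259 passed limma's adjusted p of 0.05, and 840 of these were higher and 1419 lower. Most differences were small: the median size among the changed genes was 0.25 on the log2 scale, 89 genes changed by at least 1.5-fold (29 higher, 60 lower) and 14 by at least 2-fold (3 higher, 11 lower). The 3 satellite alpha values lay on one side of the 3 GFP values in 37.6% of tested genes, against 10% by chance. The count depended on which array was left out. It was 1216 without GFP replicate 1, 1396 without SATalpha replicate 1 and 2520 without SATalpha replicate 3. Fewer arrays also give less power. Of the 2259 genes, 1031 passed in the same direction whichever of the 6 arrays was left out.

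CRYM, which encodes a cytosolic thyroid hormone binding protein, had the largest increase, from 8.49 ± 0.06 to 9.62 ± 0.02 (mean ± SD, n = 3), a log2 difference of 1.14 (SE 0.05, limma adjusted p = 3.73e-09). FEM1B, a substrate receptor of a ubiquitin ligase, rose by 1.03 (SE 0.06, adjusted p = 1.12e-07). TLR3, a receptor for double-stranded RNA, rose from 6.17 ± 0.09 to 7.04 ± 0.08, by 0.86 (SE 0.07, adjusted p = 3.23e-06). MDM2, the ubiquitin ligase that restrains p53, rose by 0.77 (SE 0.08, adjusted p = 2.83e-05), and the lowest value among its other probe sets was 0.25. The other large increases were EPM2AIP1 (1.01), the TFIID subunit TAF13 (0.94), EID3 (0.92), SPACA6 (0.90), the RNA-binding protein HNRNPA3 (0.88) and OGA, which removes O-GlcNAc from proteins (0.79). Their adjusted p-values ran from 1.27e-07 to 0.000118. Probe sets disagreed for 3 of these genes. The other EPM2AIP1 probe set differed by 0.10, those of HNRNPA3 by 0.06 to 0.39 and those of OGA by -0.04 to 0.76. HNRNPA3 was no longer past the threshold when probe sets that can match several transcripts were left out (0.06, limma adjusted p = 0.544, with 3.60e-09 to 0.544 over all alternatives).

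The largest decrease was in the probe set of RAP1A, a small GTPase, which fell from 14.32 ± 0.01 to 12.64 ± 0.07 (mean ± SD, n = 3), a log2 difference of -1.68 (SE 0.03, limma adjusted p = 6.52e-13). With GFP this probe set stood at the maximum of each array (14.32, 14.32 and 14.31), where normalized signals can reach a ceiling, so the size of the difference may be understated and its SE may be too small. The 3 other RAP1A probe sets did not fall and differed by 0.02 to 0.21. BHLHE41 and CIART, both transcriptional repressors of the circadian clock, fell by 1.42 (SE 0.06, adjusted p = 1.05e-08) and 1.29 (SE 0.07, adjusted p = 5.87e-08). BHLHE41 went from 9.04 ± 0.14 to 7.62 ± 0.04. EGR1, an immediate early transcription factor, fell from 7.70 ± 0.02 to 6.42 ± 0.07, a difference of -1.28 (SE 0.06, adjusted p = 1.61e-08). The GTPase ARL14 (-1.44), the adhesion protein FLRT3 (-1.37), secretogranin SCG2 (-1.22), ribokinase RBKS (-1.14), the TNF receptor adaptor TRAF1 (-1.05) and the steroid reductase AKR1D1 (-1.04) also fell, with adjusted p-values from 7.21e-08 to 1.28e-05. The other RBKS probe set differed by -0.09.

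**Figure D1:**
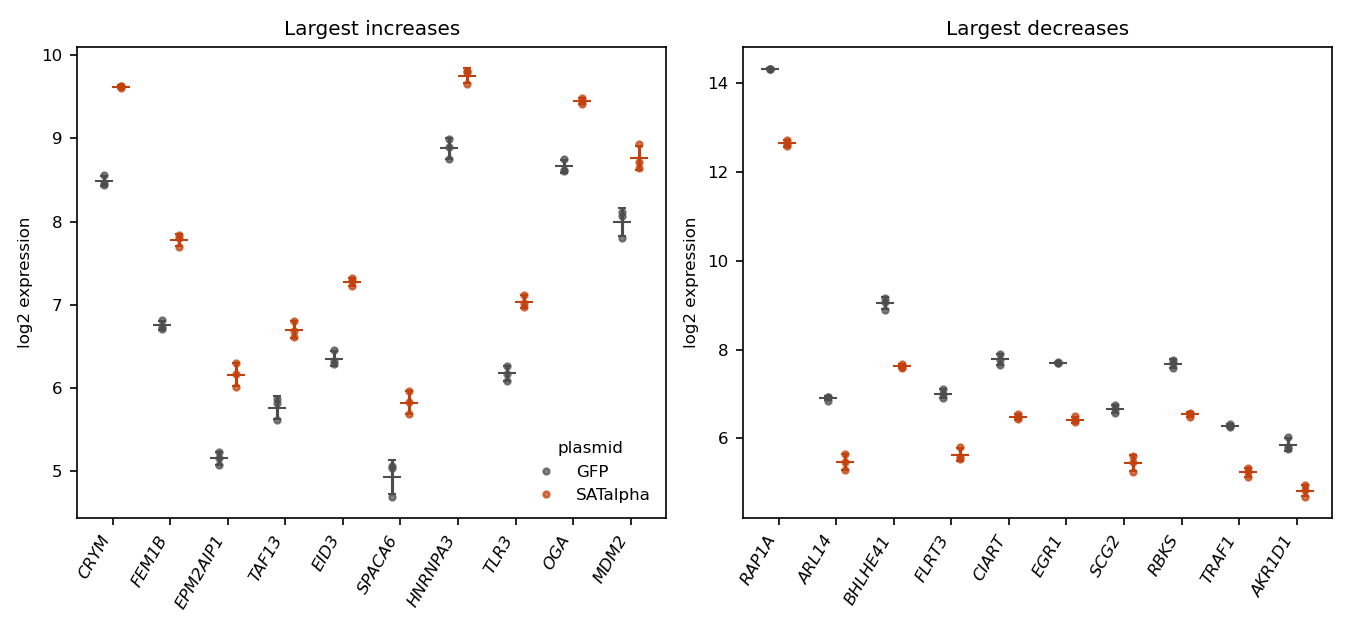
Log2 expression of the 10 genes with the largest increases (left) and the 10 with the largest decreases (right) on each array, with GFP in grey and satellite alpha in orange. Points are arrays, horizontal bars are group means and error bars are SD (n = 3). The groups do not overlap for any of the 20 genes, as the rule for naming them required, and RAP1A stands highest at 14.32 with GFP.

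Genes of mitosis formed the clearest group. Of the 24 tested members of the G2/M and mitosis list, 21 fell and 0 rose, with a median log2 difference of -0.40 (camera adjusted p = 7.60e-18; adjusted p = 0.145 with an estimated correlation). The mitotic kinase AURKA fell from 10.00 ± 0.04 to 9.22 ± 0.08 (mean ± SD, n = 3), a difference of -0.78 (limma adjusted p = 1.12e-07). The mitotic cyclin CCNB1 fell by 0.67, the anaphase activator CDC20 by 0.68 and the spindle protein HMMR by 0.66. Of the 21 genes, 20 passed whichever array was left out. The G1/S and DNA replication list did not pass (camera adjusted p = 0.348). Of its 27 tested members 3 rose, 2 fell and 22 did not pass, and its median was -0.0047 while its mean was 0.02. GINS3, a subunit of the replicative helicase, rose by 0.52 (adjusted p = 4.90e-06), and CDC6, which loads that helicase, rose by 0.24 (adjusted p = 0.00389), although another CDC6 probe set differed by 0.00067. As the mean of all its probe sets, CDC6 differed by 0.12 and lost the call (limma adjusted p = 0.0616). GINS1, of the same complex as GINS3, fell by 0.20 (adjusted p = 0.0102), a call lost without GFP replicate 1 (-0.20) or SATalpha replicate 1 (-0.18), and its other probe sets differed by -0.15 and 0.09 (mean of all probe sets -0.09, not past the threshold). MCM7, a helicase subunit, rose by 0.12 (adjusted p = 0.0298). That call was lost without GFP replicate 1, 2 or 3 (0.14, 0.11 and 0.11) or SATalpha replicate 1 (0.11), and under quantile normalization (0.10), a replicate block or no mean-variance trend (0.12 in both). The nuclease FEN1, chosen after its value was seen, fell by 0.14 (adjusted p = 0.0496). Its call was lost without GFP replicate 1, 2 or 3 (-0.14, -0.14 and -0.13) or SATalpha replicate 1 or 2 (-0.16 and -0.10). It was also lost with no filter, a replicate block or no mean-variance trend (-0.14 in each).

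The centromere and kinetochore list was lower as a set. Of 31 tested members 13 fell, 2 rose and 16 did not pass, with a median of -0.13 (camera adjusted p = 0.0198; adjusted p = 0.190 with an estimated correlation). The call ended when the lowest 60% of genes were left out (median -0.09, camera adjusted p = 0.114). HJURP, the chaperone that deposits CENPA at centromeres, fell by 0.61 (limma adjusted p = 6.06e-06). NDC80, which binds spindle microtubules, also fell by 0.61 (adjusted p = 1.31e-05), and CDCA8, of the chromosomal passenger complex, by 0.53 (adjusted p = 3.58e-05). CENPA, the centromeric histone H3 variant, fell from 9.57 ± 0.07 to 9.13 ± 0.07 (mean ± SD, n = 3), by 0.44 (adjusted p = 3.99e-05). CENPB, which binds a motif in satellite alpha, had a difference of -0.16 (SE 0.11, adjusted p = 0.337). CENPC, which binds CENPA nucleosomes, had one of -0.20 (SE 0.10, adjusted p = 0.170). Neither passed the threshold. Whichever array was left out, 7 of the 15 changed members passed.

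Heterochromatin genes did not pass as a set. Of 28 tested members 1 rose, 2 fell and 25 did not pass. The median and mean were both -0.02. Camera placed the list only nominally higher than other genes, far from the threshold (adjusted p = 0.989). HELLS, a chromatin remodeller, rose by 0.28 (limma adjusted p = 0.00464), and CBX3, a heterochromatin protein, fell by 0.18 (adjusted p = 0.00451), although another of its probe sets differed by 0.03. SUV39H1, a histone H3 methyltransferase of heterochromatin, differed by -0.15 (SE 0.06, adjusted p = 0.116), which did not pass. In the histone list 5 members rose and 3 fell of 13 tested (camera adjusted p = 0.424), with a median of 0.02 and a mean of -0.03. H2AC11 fell by 0.81 and H4C3 by 0.52, while H2AC6 rose by 0.42. A probe set listed for both H4C14 and H4C15 was outside the gene-level test and chosen after its value was seen. It fell by 1.61 (adjusted p = 1.47e-07 by limma over all non-control probe sets). The other H2AC11 probe set differed by -0.0046. H2BC12 differed by 0.24 in its brightest probe set and by -0.29 in the other. The DNA repair list had 5 lower and 0 higher members of 24 (median -0.08, camera adjusted p = 0.0615). They included H2AX (-0.43), the end-joining factor XRCC4 (-0.54) and RAD54B (-0.60), and these 3 passed whichever array was left out.

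Interferon-stimulated genes were higher as a set. Of 31 tested members 20 rose, 3 fell and 8 did not pass, with a median of 0.23 (camera adjusted p = 2.17e-13; adjusted p = 0.190 with an estimated correlation). Adjusted over the list alone, 21 rose and 4 fell. IFIT2, which binds viral RNA, rose from 11.35 ± 0.01 to 12.08 ± 0.06 (mean ± SD, n = 3), by 0.73 (limma adjusted p = 1.61e-08). The antiviral enzyme RSAD2 rose from 9.52 ± 0.05 to 10.22 ± 0.06, by 0.70 (adjusted p = 1.53e-07), and IFIT3 rose by 0.57 (adjusted p = 1.18e-06). IFIT5 rose by 0.46, although its other probe set differed by -0.06. Chosen after their values were seen, the 3 members that fell were IRF9 (-0.26), a subunit of the factor that drives these genes, CXCL11 (-0.44) and DDX60 (-0.18), and of these IRF9 alone passed whichever array was left out. ISG15, also chosen after its value was seen, was at 13.06 with GFP and differed by 0.06, not past the threshold (adjusted p = 0.185). Of the 23 changed members, 18 passed whichever array was left out.

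The list of nucleic acid sensing did not pass (camera adjusted p = 0.0585). It had 5 higher and 2 lower members of 17, or 6 and 3 adjusted over the list alone. Besides TLR3, the nuclease SAMHD1 rose by 0.31 and the RNA-activated kinase EIF2AK2 by 0.22, whereas DHX58, a helicase of the RIG-I family, fell by 0.44 (limma adjusted p = 1.74e-05). NF-kB and inflammatory genes had 2 higher and 8 lower members of 19 (median -0.11, camera adjusted p = 0.348). RELB, an NF-kB subunit, fell by 0.65 (adjusted p = 1.70e-05), the feedback inhibitor TNFAIP3 by 0.44 and the subunit NFKB1 by 0.38, while the chemokine CCL20 rose by 0.62 (adjusted p = 0.000215). Of the 10 changed members, 6 passed whichever array was left out.

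**Figure D2:**
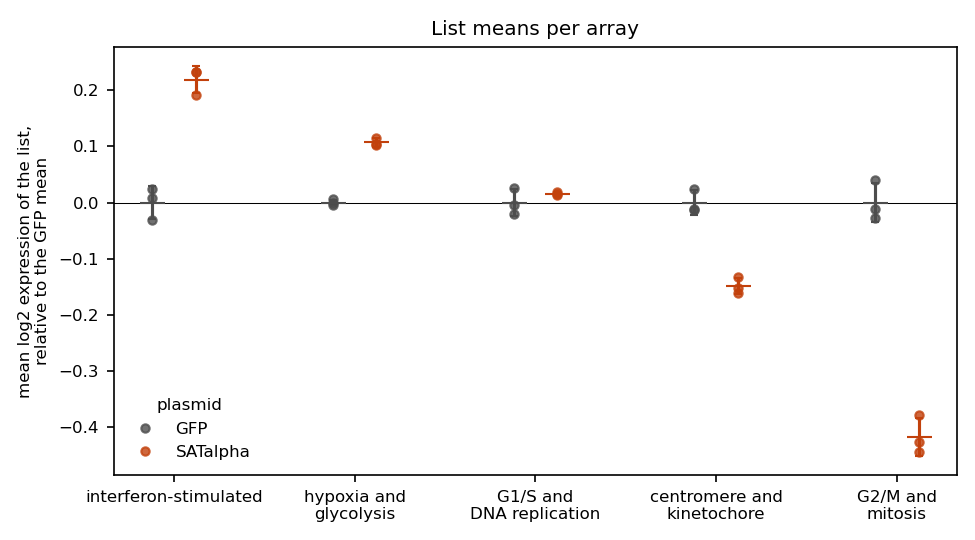
Mean log2 expression of the tested members of 5 gene lists on each array, relative to the GFP mean, with GFP in grey and satellite alpha in orange. Points are arrays, horizontal bars are means and error bars are SD (n = 3). The satellite alpha arrays lie between -0.45 and -0.38 for G2/M and mitosis, between 0.19 and 0.23 for interferon-stimulated genes, and between 0.01 and 0.02 for G1/S and DNA replication.

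Targets of p53 moved both ways, with 2 higher and 7 lower members of 23 (median -0.08, camera adjusted p = 0.0772). AEN, DDB2 and SESN2 fell by 0.64, 0.52 and 0.55 while MDM2 rose. In the apoptosis list 5 members rose and 3 fell of 19 (camera adjusted p = 0.0615). PMAIP1, a pro-apoptotic BCL2 family member, rose by 0.66 (limma adjusted p = 3.74e-07), the caspase-8 inhibitor CFLAR by 0.29 and HRK by 0.37, while BIRC2 fell by 0.21. The senescence and secretory phenotype list had 1 higher and 1 lower member of 17 (camera adjusted p = 0.424). The cyclin kinase inhibitor CDKN2B fell by 0.31 (adjusted p = 0.00384). CXCL8 differed by 0.14, past the threshold with all arrays but not when GFP replicate 1, GFP replicate 2, SATalpha replicate 1 or SATalpha replicate 2 was left out (0.15, 0.12, 0.13 and 0.11).

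Hypoxia and glycolysis genes were higher as a set, with 5 higher, 0 lower and 16 not past the threshold of 21 tested and a median of 0.11 (camera adjusted p = 0.000299; adjusted p = 0.145 with an estimated correlation). Adjusted over the list alone, 6 rose and 1 fell. ADM, a secreted vasodilator peptide induced by hypoxia, rose from 9.78 ± 0.02 to 10.53 ± 0.07 (mean ± SD, n = 3), by 0.75 (limma adjusted p = 6.33e-08), and it alone passed whichever array was left out. The glycolytic genes HK2 (0.25), ENO1 (0.13) and LDHA (0.11) rose by less. HK2 and LDHA lost the call without GFP replicate 1 (0.22 and 0.11), and ENO1 lost it without GFP replicate 2 or SATalpha replicate 1 (0.13 and 0.12).

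Lists of stress responses were not called by camera. In the unfolded protein and integrated stress response list 4 members rose and 7 fell of 22, or 5 and 7 adjusted over the list alone (median -0.07, camera adjusted p = 0.424). TRIB3, ASNS and XBP1 fell by 0.36, 0.29 and 0.27, and PPP1R15A, which guides the phosphatase of eIF2 alpha, rose by 0.33. The other TRIB3 probe set differed by -0.04. Heat shock genes had 2 higher and 2 lower members of 16 (camera adjusted p = 0.938), of which the chaperone DNAJA1 (0.20) alone passed whichever array was left out. Its 4 other probe sets differed by -0.01 to 0.07 and did not pass. Genes of oxidative stress and NRF2 had 4 higher and 2 lower members of 18 (camera adjusted p = 0.0772). OSGIN1 fell by 0.59, and the quinone reductase NQO1 and peroxiredoxin PRDX1 rose by 0.16 and 0.15. Immediate early genes had 4 higher and 2 lower members of 17, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0772). Against the fall of EGR1, IER3 rose by 0.61 (limma adjusted p = 3.16e-08) and JUN by 0.40, although the lowest of the other JUN probe sets was at -0.26. DUSP5 fell by 0.31.

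Genes of cell identity showed small differences. No tested member of the retinal pigment epithelium list passed by limma (0 of 11, with 1 at an unadjusted p under 0.05 and 0 by the unmoderated test). Its median was -0.09 and its mean -0.03. Camera placed it only nominally higher than other genes, far from the threshold (adjusted p = 0.938). EZR differed by 0.10 (SE 0.04, limma adjusted p = 0.126) and ITGAV by -0.11 (SE 0.05, adjusted p = 0.149). ITGAV passed when GFP replicate 2 was left out (-0.17, adjusted p = 0.0435, with 0.0435 to 0.898 over all alternatives). Another ITGAV probe set rose by 0.27 (adjusted p = 0.0315 by limma over probe sets), so its direction is uncertain. RPE65, with a mean log2 level of 3.41, and CDH1, with 3.87, lay below the floor and were not tested. The mesenchymal and EMT list had 2 higher and 2 lower members of 17 (camera adjusted p = 0.938). Smooth muscle actin ACTA2 fell by 0.52 (adjusted p = 1.40e-05) and alone passed whichever array was left out. CDH2 and VIM both differed by 0.02 (adjusted p = 0.725 and 0.751). In the epithelial junction and keratin list 4 members fell and 0 rose of 13 (median -0.02, camera adjusted p = 0.386), among them KRT18 (-0.21), CLDN1 (-0.36) and KRT7 (-0.21).

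TGF-beta targets had 4 higher and 4 lower members of 19 (camera adjusted p = 0.424), and these 8 passed whichever array was left out. The inhibitors SMAD7, SKIL and BAMBI rose by 0.43, 0.55 and 0.26, while LTBP2 fell by 0.30. YAP and SRF targets had 4 higher and 5 lower members of 18, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.938). Their median was -0.01 and their mean -0.02, and camera placed the list only nominally higher than other genes, far from the threshold. CCN1 rose by 0.38 (limma adjusted p = 6.06e-06) and ANKRD1 by 0.23, and FHL2 and AMOTL2 fell by 0.36 and 0.34, although another AMOTL2 probe set differed by 0.18. In the extracellular matrix and basement membrane list 2 members rose and 0 fell of 22 (camera adjusted p = 0.0772), namely the metalloproteinases ADAMTS1 (0.50) and MMP14 (0.35). The complement and macular degeneration list had 4 higher and 1 lower member of 12 (camera adjusted p = 0.0772). CD55, which restrains complement, rose by 0.37, and the proteases C1S and C1R rose by 0.24 and 0.20. CLU fell by 0.28, although its other probe set differed by 0.06.

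Cholesterol synthesis had 1 higher (INSIG1, 0.24) and 1 lower (HSD17B7, -0.36) member of 16 (camera adjusted p = 0.481), and both lost the call without GFP replicate 1 (0.18 and -0.32). INSIG1 also lost it without SATalpha replicate 1 (0.24). Oxidative phosphorylation had 0 higher and 2 lower members of 20, SDHA (-0.18) and CYC1 (-0.13), and adjusted over the list alone 0 passed, with 3 at an unadjusted p under 0.05 by limma and 0 by the unmoderated test. Its median and mean were both -0.01, and camera placed it only nominally higher than other genes, far from the threshold (adjusted p = 0.828). Ribosomal protein genes had 1 lower member of 24, RPL13 (-0.13), and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05 by limma and 0 by the unmoderated test (camera adjusted p = 0.938). SDHA, CYC1 and RPL13 lost the call without GFP replicate 1 (-0.15, -0.12 and -0.13), without SATalpha replicate 2 (-0.14, -0.11 and -0.10) and without at least 1 further array. The lysosome and autophagy list had 6 higher and 3 lower members of 20, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.759). Its median was -0.05 and its mean -0.0025, and camera placed it only nominally higher than other genes, far from the threshold. Of the 9 changed members, 3 passed whichever array was left out. GABARAPL1 rose by 0.35 and CTSL by 0.22, and HEXA fell by 0.19.

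Markers of other cell types were mostly too dim to be tested. By limma, 0 of 3 tested macrophage and leukocyte genes and 0 of 4 tested endothelial genes passed, with 0 at an unadjusted p under 0.05 and 0 by the unmoderated test in either list. CSF1R differed by -0.13, CD68 by -0.06, TIE1 by 0.13 and PECAM1 by 0.19. Of 3 tested photoreceptor and neural retina genes, the phosphodiesterase PDE6B fell by 0.41 (limma adjusted p = 0.00284).

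**Figure D3:**
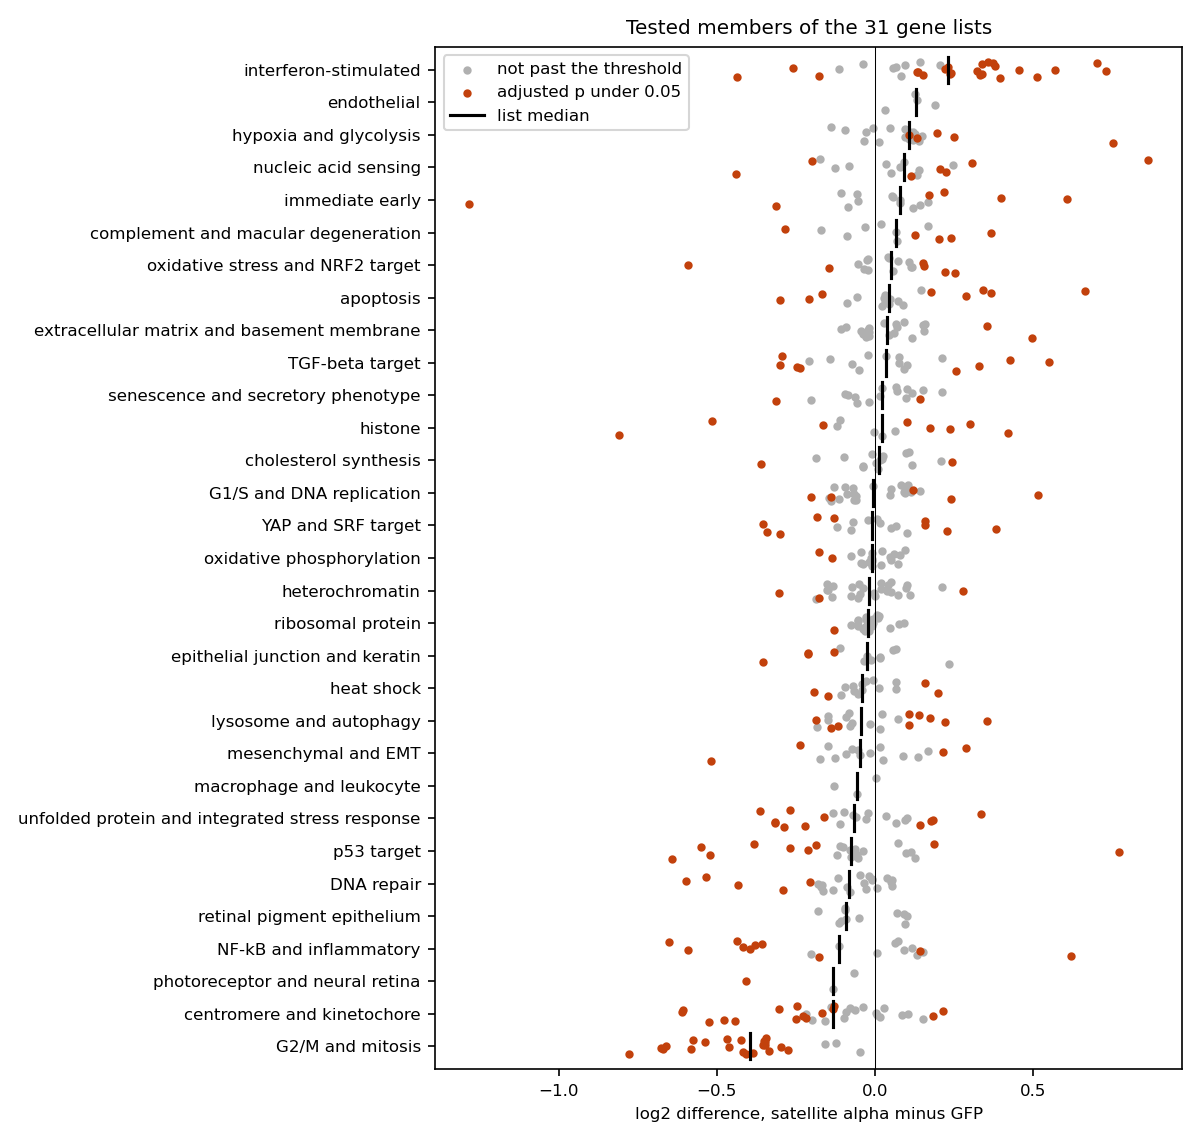
Log2 difference (satellite alpha minus GFP, x axis) of each tested member of the 31 lists, sorted by list median (black bars). Orange points had a limma adjusted p under 0.05 and grey points did not. The G2/M and mitosis members all lie below 0 with a median of -0.40, and interferon-stimulated genes have the highest median at 0.23.

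Camera at the preset correlation called 4 of the 28 tested lists, 2 higher and 2 lower. With an estimated correlation it called 0, and 4 had an unadjusted p under 0.05. Fry called 13, which were these 4 together with the lists of epithelial junction, NF-kB, nucleic acid sensing, p53, DNA repair, unfolded protein, extracellular matrix, complement and apoptosis genes. Whichever array was left out, the threshold was passed by 2 of 5 changed G1/S members, 5 of 7 in nucleic acid sensing, 6 of 9 p53 targets, 5 of 8 apoptosis genes and 5 of 8 histones. It was passed by 9 of 11 unfolded protein genes, 4 of 6 oxidative stress genes, 5 of 6 immediate early genes, 7 of 9 YAP and SRF targets and 4 of 5 complement genes, and by 2 of 3 heterochromatin genes, 3 of 4 epithelial genes and 1 of 2 senescence genes. Where no count adjusted over the list alone is given above, it equalled the count over all genes, except that the G1/S list had 3 higher and 1 lower and the centromere list 3 higher and 13 lower. Further probe sets of named genes also disagreed with the one tested. The most distant was on the other side of 0 for CDC20 (0.04), HEXA (0.16), KRT8 (0.30), LAMP2 (-0.28), HSPD1 (-0.08) and AKR1C3 (-0.07). KRT8 was counted as lower (-0.13), but its most distant probe set passed as higher (adjusted p = 0.0247 by limma over probe sets). LAMP2 was counted as higher (0.17), but another of its probe sets passed as lower (-0.20, adjusted p = 0.0245 by limma over probe sets). Among named genes that did not pass, the most distant probe set was also on the other side of 0 for ITGAV (0.27), TIE1 (-0.41), EZR (-0.04), CD68 (0.01), SUV39H1 (0.0012) and VIM (-0.0023). The most distant probe set was on the same side but much smaller for CFLAR (0.05), GABARAPL1 (0.04), SMAD7 (0.11), MMP14 (0.12), CD55 (0.13), XRCC4 (-0.0074), EGR1 (-0.13), BHLHE41 (-0.20), TRAF1 (-0.36), PDE6B (-0.06), KRT18 (-0.09), CLDN1 (-0.10), LTBP2 (-0.14), TNFAIP3 (-0.20) and DHX58 (-0.09).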

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

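Signal outside the gene-level comparison was tested with limma over all 49293 non-control probe sets, without the filter on dim genes, and its probe sets were singled out after their values were seen. Of the 2473 probe sets that the gene annotation did not list, 160 passed limma's adjusted p of 0.05 (85 higher, 75 lower). Among them the probe set with the largest increase rose by 2.50 on the log2 scale, or 5.66-fold, higher in 3 of 3 arrays and more than any named gene. The 2 with the largest decreases fell by 2.32 and 1.48, each lower in 3 of 3 arrays. These are unnamed here. Of the 1832 probe sets with several gene symbols, 146 passed (91 higher, 55 lower), and no gene-level value is taken from them.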

How the results depend on the processing

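The alternatives were planned before the data were examined. Of 1826 refits of the 125 named genes, 1713 kept direction and side of the threshold, 111 kept direction and lost the threshold, 1 gained it and 1 reversed: H2BC12 as the mean of its probe sets was at -0.028 (limma adjusted p = 0.789, with 7.19e-05 to 0.789 over all alternatives), since these disagree. Quantile normalization and median centring gave 2311 and 2303 changed genes and altered no call among the 28 lists. Counts moved with the unit or the criterion: 4375 probe sets in place of genes (2137 higher, 2238 lower), 717 genes by the unmoderated test (246 and 471) and 89 at 1.5-fold (29 and 60). Array weights gave 3328. Leaving out each array gave 1216 to 2520 changed genes, 474 to 898 higher and 742 to 1622 lower, and 4 to 7 called lists. Higher and lower counts were below the others without GFP replicate 1. List counts were 8 with no filter, 0 with an estimated correlation and 13 with fry. With an estimated correlation the 4 lists called at the preset correlation did not pass. That setting changes camera's p alone, so the list medians could not move. They were 0.23 for interferon-stimulated, -0.40 for G2/M, -0.13 for centromere and 0.11 for hypoxia genes. In the same order the estimated correlations were 0.163, 0.147, -0.0050 and -0.0243, against a preset of 0.01. The centromere and hypoxia estimates lay below the preset, which argues against a higher correlation as the cause of their lost calls. At an estimated correlation, camera also uses the few residual degrees of freedom of the arrays in place of those from the number of genes. A p can therefore rise without a higher correlation, and a lost call does not by itself show that members vary together. How much each part added for each list was not tested. Centromere genes without the lowest 60% had a median of -0.094 (camera adjusted p = 0.114, with 0.000347 to 0.190 over all alternatives); over the other alternatives of camera with preset correlation the call held, and the cause was not tested. With the replicate block 1300 genes passed (483 higher, 817 lower). Same-numbered arrays did not deviate together (correlations -0.0035, -0.24 and -0.29), and not every array correlated best with its own number. So few correlations cannot show whether the numbers pair the wells. Pseudocount alternatives were not run because the values are log2. Without scanner files, signal over background was not known. Among tested genes, a 1.2-fold change was recovered in 38.2% of simulated cases, and genes below the filter were not simulated. Without a filter 2044 genes passed.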

Other observations

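The gene groups in these first paragraphs were chosen after seeing the data and adjusted over 12 such groups, so they are not independent of the results. Antigen presentation genes rose as a group: 13 of 21 were higher and 0 lower, with a median of 0.16 (camera adjusted p = 6.73e-10; adjusted p = 0.0238 with an estimated correlation). BTN3A2, a butyrophilin of the major histocompatibility region, rose from 6.45 ± 0.06 to 7.15 ± 0.08 (mean ± SD, n = 3), by 0.70 (limma adjusted p = 1.11e-05). HLA-E rose by 0.35, the peptide transporter TAP2 by 0.33 and NLRC5, an activator of class I genes, by 0.26. B2M differed by 0.02 (limma adjusted p = 0.806) and did not pass. Circadian clock genes fell: 7 of 14 were lower and 0 higher, with a median of -0.24 (camera adjusted p = 3.68e-05; adjusted p = 0.0552 with an estimated correlation). Besides BHLHE41 and CIART these were PER2 (-0.55), NOCT (-0.51), DBP (-0.49), CRY1 (-0.40) and BMAL1 (-0.25), although the other PER2 probe sets ran from -0.77 to 0.14. BHLHE41 and CIART, which prompted the group, were then left out, and of the other 12 genes 5 were lower and 0 higher, with a median of -0.21 (camera, unadjusted 0.00227, and unadjusted 0.0324 with an estimated correlation).

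Kinesins, the motor proteins of microtubules, had 10 lower and 1 higher of 29 (median -0.10, camera adjusted p = 0.0314; adjusted p = 0.170 with an estimated correlation). KIF18A fell by 0.66 and KIF2C by 0.55. Tubulins and gamma-tubulin complex proteins had 5 lower and 0 higher of 17 (median -0.12, camera adjusted p = 0.0268; adjusted p = 0.170 with an estimated correlation), among them TUBB3 (-0.37) and TUBB4B (-0.27), although another TUBB4B probe set differed by 0.08. Host genes of small nucleolar RNAs had 3 lower and 0 higher of 8 (camera adjusted p = 0.0406; adjusted p = 0.170 with an estimated correlation). The lower ones were SNHG12, SNHG8 (-0.20) and SNHG29 (-0.12). The 2 probe sets of SNHG12 alone fell by 0.82 and 0.89, but 1 listed for it together with another gene rose by 0.83, so its direction is uncertain. SNHG12 had by far the largest difference of the group. The group was not tested without it, so the group's count and call are uncertain too. The other SNHG29 probe sets ran from -0.13 to 0.17. Zinc finger, metallothionein, proteasome, ubiquitin-conjugating and translation initiation genes did not pass (camera adjusted p = 0.275, 0.991, 0.787, 0.819 and 0.532). When the centromere list was split, its 13 members that peak in mitosis had a median of -0.25 with 9 lower (camera adjusted p = 3.87e-06; adjusted p = 0.144 with an estimated correlation). The 18 others had a median of -0.03 with 2 higher and 4 lower (camera adjusted p = 0.991). Whether the parts differ was not tested.

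Of the tests that follow, those on leaving out 1 array and on other splits of the arrays for lists were written before their results were seen, and the others after. The real split gave 2259 changed genes, and the highest of the other 9 splits gave 0. It gave 4 called lists, and the highest other gave 2. In both cases 1 of the 10 splits, the real one, gave a result as large, and 10 splits cannot give a share under 0.05.

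Interferon-stimulated genes were higher with satellite alpha (median 0.23). The median of all tested genes (-0.0247) is held near 0 by normalization and does not test for an offset. An offset left by the authors' normalization, shared by genes of similar level, would cancel when each member is set against the 200 other genes nearest in mean level. The 31 members still differed from them by a median of 0.24 (95% bootstrap interval over genes, 0.14 to 0.35). The medians of the matched genes ran from -0.055 to 0.012. The near-equal quantiles of the arrays hold genes of similar level near 0 as well. The comparison therefore had to return about the list's own median and does not decide whether an offset was left. No single array carried the change, since the lowest list median with 1 array left out was 0.21. More plasmid DNA in the cells of 1 group cannot be told apart from satellite alpha itself, because 0 probe sets were named for GFP and plasmid uptake was not measured. A response to satellite alpha transcripts or DNA therefore remains an untested hypothesis, and the rise of TLR3 does not decide it.

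Mitotic genes were lower (median -0.40). If a lower share of cycling cells lowered both lists by about as much, the G1/S and G2/M medians would lie close together. The G1/S list lay above the G2/M list by 0.391 (95% bootstrap interval over genes 0.282 to 0.529). That interval does not measure the spread between wells. Whether fewer cycling cells would lower both lists equally is not known here, so the difference does not decide that cause. No single array carried the fall of mitotic genes, as the highest G2/M list median with 1 array left out was -0.36. Clock genes were lower as a group (camera adjusted p = 3.68e-05, unadjusted 9.20e-06), a call lost with an estimated correlation (adjusted p = 0.0552) and partly circular, since BHLHE41 and CIART prompted it. A difference in harvest time or density of the wells was not recorded and cannot be told apart from the plasmid with these files. Other biological explanations were not tested.

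The RAP1A probe set was the brightest on each GFP array (rank 1) and ranked 227 to 275 with satellite alpha. A fall of the RAP1A mRNA read by its other probe sets would show in them, but their lowest 95% bound was -0.12. Their median was 0.0256, consistent with this probe set reading another transcript. Which transcript it reads was not tested, and it may be a form of RAP1A that the other probe sets do not cover. Across the array, 37 of 11734 genes with more than 1 probe set had probe sets past the threshold in both directions.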
